A study of Homo sapiens with 9 samples.

How the data were processed

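Total RNA from NB4, K562 and U937 cells was extracted with Trizol, cleaned on columns with DNase treatment, labelled as biotinylated cRNA and hybridized to Illumina bead arrays, per the labels' protocols. There were 9 arrays, 1 for each of the 3 lines with each of 3 treatments, namely no inhibitor, MS-275 or SAHA at 5 µM for 6 h. The inhibitors were dissolved in DMSO, per the labels, which do not state whether untreated cells received it, so an effect of the solvent cannot be separated from that of the inhibitors. The labels number every array as the first replicate, so the pairing of treated and untreated arrays came from the cell line. No slide, chip or date is recorded, so a batch could not be tested.

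The authors deposited a table of bead intensity per probe that is not background-subtracted and not normalized, with array medians from 104 to 139, as found from the values. Each intensity has a detection p-value, which the authors deposited in steps of 1/708 and which gives the rank of the probe among negative controls as far as the values show. The authors also deposited processed log2 values made with lumi, per the submitters' processing notes, which give no version, scale or normalization. These log2 values equalled the quantile-normalized log2 of the intensity table within 0.001 for all 199593 values, so they hold no background correction. The tables name probes differently and were linked by the ranks of each probe on the 9 arrays, which matched exactly 1 probe of the other table for all 22177 probes. The gene names of 19708 probes came from the platform's annotation, 0 probes had several symbols and 2469 had none here, and the Entrez identifiers of 19688 were found in a RefSeq gene table, with 0 symbols changed. Gene coordinates were not used here, except for which genes neighbour each other.

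The intensities were background-corrected with limma's nec function, which infers the negative controls from the detection p-values, with an offset of 16, then quantile-normalized and put on the log2 scale. A probe was tested if its detection p-value was under 0.05 on at least 3 of 9 arrays, which left 13836 probes, 12550 with a gene symbol and 1286 without. The brightest probe stood for each of 11228 genes, 1108 of which had more than 1 probe. On all 9 arrays 9102 probes were detected, and 6493 on no array. Arrays of one line correlated at 0.942 to 0.968 and arrays of different lines at 0.736 to 0.890. With the treatment means removed, arrays of the same line correlated at 0.865 to 0.933 and arrays of different lines at −0.651 to −0.171, and the line was therefore used as a block.

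Genes were tested with limma in a model of treatment and cell line with 4 residual degrees of freedom, which takes the 3 treatments as sharing 1 estimate of the spread, and two-sided p-values were adjusted by the method of Benjamini and Hochberg over all genes tested. A gene counted as changed at an adjusted p under 0.05. Errors of log2 changes are standard errors from this model, and ranges over lines are the lowest and highest of the 3 lines. With 3 lines and no replicate within a line, the tests address changes shared by these lines. Line dependence was tested with an F test of the interaction of line with treated against untreated, with 3 residual degrees of freedom, where the residual holds the difference between the inhibitors. Both comparisons with untreated cells use the same control arrays, and the correlation this gives was estimated from 50 simulated sets of unchanged arrays.

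Before the data were examined, 29 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists were HDAC inhibitor response genes, cyclin-dependent kinase inhibitors, G1/S and DNA replication, G2/M and mitosis, pro-apoptotic BCL2 family, anti-apoptotic genes, death receptors and ligands, classical HDACs, histone acetyltransferases and bromodomain genes, and DNA and histone methylation genes. Others covered linker and variant histones, myeloid differentiation, erythroid, megakaryocytic, haematopoietic and leukaemia regulators, MYC and ribosome biogenesis, type I interferon response, NF-kappaB and inflammatory cytokines, antigen presentation, heat shock and chaperones, and metallothioneins. The remaining ones were p53 targets, DNA repair, neuronal genes, T and B lymphocyte markers, epithelial and stromal markers, cytoskeleton and adhesion, cholesterol and fatty acid synthesis, and reference genes. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Some genes stand in more than 1 list.

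Named genes were the 12 with the largest rise and the 12 with the largest fall with each inhibitor and the 5 largest each way between the inhibitors, among genes past the test, with the same sign in all 3 lines and detected on all 3 arrays of the higher group. For each line, up to 5 genes each way were taken with at least a 2-fold change with both inhibitors there and a log2 change under 0.5 with both in the other lines. From each list up to 4 members with the smallest adjusted p past the test were named, or otherwise up to 2 with the largest change, and CDKN1A, MYC, HDAC1, HDAC2 and HDAC3 were always named. Genes outside the rule are marked in the text as named after their values were seen. A fold against a group with no detected array is a lower bound, taken against the intensity at the detection limit. Per line, genes detected on at least 1 of the treated and control arrays were counted at a 2-fold difference, and list medians were set against 10000 random lists matched on expression.

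Alternatives were the authors' processed values, no background correction, scaling to equal medians, an offset of 50, no detection filter, detection on all 9 arrays, the mean of a gene's probes, limma's trend and robust settings, a 2-fold minimum, no block, only the 6 arrays compared, a 1.5-fold minimum per line, and leaving out each line in turn. A model with the inhibitor difference as a further term was added after seeing the data. The steps were tested on simulated data with 200 of 11228 genes changed, where a log2 change of 1 was recovered in 42.5% of genes for SAHA against control, 43.3% for MS-275 against control and 47.5% for SAHA against MS-275, and a change of 2 in 91.1, 91.8 and 93.0%. A change of 0.5 was recovered in 1.19, 1.49 and 2.39%, with 4.4, 5.3 and 5.1 false calls on average. With 2807 genes changed, 85.5, 85.6 and 85.3% of 2-fold changes were recovered, with 3.63, 3.59 and 3.75% of calls false. A simulated list shifted by 0.5 was called in 20 of 20 runs. Genes were drawn independently in these runs, so they do not test the preset correlation. The list shifted, myeloid differentiation, had an estimated correlation of 0.147 in the data. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.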

Results

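Gene expression was measured on Illumina bead arrays in 3 human leukaemia cell lines that had been left untreated or exposed for 6 h to a histone deacetylase (HDAC) inhibitor at 5 µM. NB4 comes from an acute promyelocytic leukaemia, U937 is a monocytic line and K562 comes from a chronic myeloid leukaemia in blast crisis, although the labels call all 3 lines AML lines. SAHA (vorinostat) is a hydroxamic acid that inhibits several classes of zinc-dependent HDACs, and MS-275 (entinostat) is a benzamide that acts mainly on class I HDACs. Each treatment had 3 arrays, 1 per line, so the lines were the replicates. The treatments were tested against the variation that remained once each line's own level was taken out. Each array detected 11826 to 12705 of 22177 probes (53.3 to 57.3%), and in each line both treated arrays detected more probes than the control array. The number of arrays limits the precision, and the median standard error (SE) of a gene's log2 change was 0.17 over the 11228 genes tested.

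The series set out to compare the profiles of treated and untreated cells, and the first comparison asked which transcripts differed after SAHA. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 9.21-fold (log2 change 3.20 ± 0.30 SE, n = 3 lines, adjusted p = 0.00165), with log2 changes of 2.50 to 4.22 in the lines. MYC, which encodes a transcription factor that drives growth and proliferation, fell 7.47-fold (−2.90 ± 0.42, adjusted p = 0.00401), and MYB, which encodes a transcription factor of haematopoietic progenitors, fell 5.56-fold (−2.47 ± 0.20, adjusted p = 0.00131). CBFA2T3, a corepressor gene of blood cells, fell 10.2-fold (−3.35 ± 0.32, adjusted p = 0.00166), and NFE2, which encodes a transcription factor of erythroid cells and megakaryocytes, fell 5.84-fold (−2.55 ± 0.27, adjusted p = 0.00191). RGL1, which encodes an effector of Ras-family proteins, rose 18.8-fold (4.23 ± 0.34, adjusted p = 0.00131), although only 1 of the 3 control arrays detected it. MYC did not pass without NB4 (adjusted p = 0.0519).

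Other genes that rose in all 3 lines with SAHA were DACT3, a regulator of Wnt signalling, by 14.1-fold (3.81 ± 0.65), TUFT1 by 12.6-fold (3.65 ± 0.34) and CRISPLD2 by 10.0-fold (3.33 ± 0.36). The tight junction gene CGN rose 7.57-fold, KCTD17 7.47-fold, the calpain gene CAPN5 7.09-fold, the fatty acid transporter gene SLC27A1 6.74-fold, TSPAN33 6.64-fold and the melanosome gene PMEL 6.46-fold. DACT3, KCTD17, CAPN5, TSPAN33 and PMEL were detected on 2 of the 3 control arrays, and HPCAL4, a neuronal calcium sensor gene detected on 0 of them, rose at least 4.53-fold. Genes that fell in all 3 lines included LANCL2 (7.80-fold), KCTD15 (6.70-fold), JADE2 (6.40-fold), NRROS (6.38-fold), PLD6 (6.06-fold), the tyrosine phosphatase gene PTPN7 (5.99-fold, with −0.33 on another probe), the zinc-finger factor gene ZEB2 (5.60-fold) and ARMC5 (5.46-fold). LANCL2 was still detected on 1 SAHA array and KCTD15 on 2. Of these genes CGN, KCTD17, SLC27A1 and TSPAN33 did not pass without NB4, nor TSPAN33 without K562 or DACT3 without U937.

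Of the 11228 genes, 2665 changed with SAHA at an adjusted p under 0.05, 1342 upward and 1323 downward (50.4% up), and 4144 had an unadjusted p under 0.05. At least a 2-fold change was found in 594 of the genes that rose and 486 of those that fell. With the arrays scaled to equal medians in place of quantile normalization, 998 genes rose and 1804 fell (35.6% up). The count was 887 without NB4, 1681 without K562 and 1069 without U937, and 101 without the cell line as a block.

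**Figure D1:**
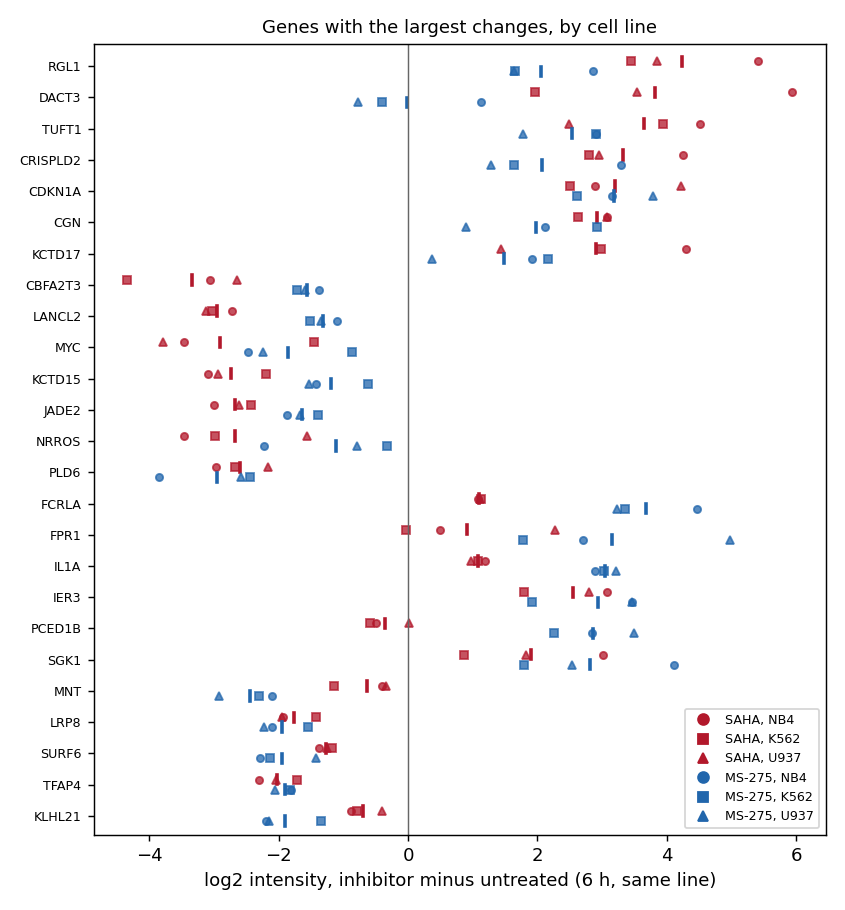
Log2 change from the untreated control of the same line (x axis) for the 25 named genes with the largest changes (y axis), with SAHA in red and MS-275 in blue, circles for NB4, squares for K562, triangles for U937 and a vertical bar at the mean of the 3 lines. CDKN1A lay between 2.50 and 4.22 in all 3 lines with either inhibitor, whereas DACT3 had means of 3.81 with SAHA and −0.02 with MS-275.

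Among 18 genes known to respond to HDAC inhibitors, 9 rose with SAHA and 0 fell, or 12 and 0 adjusted over the list alone, with a median log2 change of 0.84. The camera set test gave an adjusted p of 0.000102, and adjusted p = 0.208 with an estimated correlation. That estimate was −0.00145 for this list, under the preset 0.01, so the larger p does not come from a higher correlation. Besides CDKN1A, TUBB3, which encodes a neuronal beta-tubulin, rose 4.18-fold (2.06 ± 0.25, adjusted p = 0.00258) and the glutaredoxin gene GLRX rose 3.73-fold (1.90 ± 0.30, adjusted p = 0.00533). Of 13 genes of cholesterol and fatty acid synthesis, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 1.03 and a camera adjusted p of 0.0218 (adjusted p = 0.391 with an estimated correlation). Risers included IDI1 (2.63-fold, 1.40 ± 0.17), which encodes an isomerase of the isoprenoid pathway, SREBF1 (2.33-fold, 1.22 ± 0.17), which encodes a lipogenic transcription factor, and the lanosterol synthase gene LSS (2.07-fold). The gene that fell was the fatty acid synthase gene FASN (−0.66 ± 0.16), named after its value was seen.

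In the list of MYC and ribosome biogenesis genes, 10 of 21 fell with SAHA and 1 rose, or 11 and 2 adjusted over the list alone, with a median of −0.43 and a camera adjusted p of 0.014 (adjusted p = 0.379 with an estimated correlation). Besides MYC itself, the nucleolar genes PPAN (3.96-fold, −1.99 ± 0.14), RRS1 (2.85-fold, −1.51 ± 0.14) and NOP16 (2.54-fold, −1.34 ± 0.13) and the pyrimidine synthesis gene CAD (2.46-fold) fell, while MXD1, which encodes an antagonist of MYC, rose 3.81-fold (1.93 ± 0.37, adjusted p = 0.0109). Of 28 genes of G1/S and DNA replication, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of −0.34 and a camera adjusted p of 0.0218 (adjusted p = 0.424 with an estimated correlation). The CTP synthase gene CTPS1 fell 3.26-fold (−1.71 ± 0.15), the thymidylate synthase gene TYMS 1.92-fold and the helicase gene MCM2 1.65-fold. UNG fell 1.80-fold on its brightest probe (−0.85), with 0.31 on another, and TK1, named after its value was seen, rose (1.24 ± 0.30).

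Of 16 p53 target genes, 7 rose with SAHA and 1 fell, with the same counts adjusted over the list alone, a median of 0.37 and a camera adjusted p of 0.0448 (adjusted p = 0.379 with an estimated correlation). The stress-responsive sestrin genes SESN2 (3.95-fold, 1.98 ± 0.22) and SESN1 (3.26-fold, 1.70 ± 0.27) rose, and MDM2, named after its value was seen, fell (−0.95 ± 0.20). Among 12 linker and variant histones 4 rose and 0 fell, also adjusted over the list alone, with a median of 0.49, and the linker histone gene H1-10 rose 2.24-fold (1.16 ± 0.14, adjusted p = 0.0024). Its camera adjusted p was 0.0448, against adjusted p = 0.379 with an estimated correlation. Neuronal genes gave 4 risers of 16 and 0 that fell (6 and 0 adjusted over the list alone), among them SYT11 (3.47-fold, 1.79 ± 0.22) and ENO2 (3.28-fold, 1.72 ± 0.45), which like SESN2 was detected on 2 of 3 control arrays. Their median was 0.50 and their camera adjusted p 0.0448 (adjusted p = 0.391 with an estimated correlation). Restricted to probes detected on all 9 arrays, the calls for G1/S, linker histones, p53 targets and neuronal genes ended, with adjusted p up to 0.0656, 0.123, 0.0973 and 0.135 over the alternatives. Leaving out K562 also ended those for linker histones and p53 targets, and leaving out NB4 or using values without background correction that for neuronal genes.

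Cell death genes moved both ways with SAHA. Of 12 pro-apoptotic BCL2 family genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0568), with BMF up 4.36-fold (2.12 ± 0.38) and BID down 2.35-fold (−1.23 ± 0.22). BIK rose 2.74-fold, BNIP3L 2.03-fold, BAD 1.83-fold (0.26 on another probe) and BNIP3 1.67-fold, where 2 of 3 control arrays detected BMF and BIK. Of 9 anti-apoptotic genes 1 rose and 2 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.281). BCL2L1, which encodes BCL-XL, fell 2.66-fold (−1.41 ± 0.19) and CFLAR 2.58-fold, whereas MCL1 rose 1.78-fold on its brightest probe, with 0.07 on another. Of 12 death receptors and ligands 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.809). TNFSF9 rose 5.85-fold (2.55 ± 0.28), the TRAIL receptor gene TNFRSF10B 3.21-fold (0.60 on another probe), and FADD fell 1.52-fold. Of 5 cyclin-dependent kinase inhibitors 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.198), with CDKN2D up 4.55-fold (2.19 ± 0.21) and CDKN1B down 2.15-fold (−1.10 ± 0.21). Of 25 genes of G2/M and mitosis 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.169). The mitotic kinase gene PLK1 fell 2.75-fold (−1.46 ± 0.16), CCNA2 1.85-fold and CCNB1 1.75-fold, and AURKA (−0.83 ± 0.18) and CENPA (−0.57 ± 0.12) were named after their values were seen. CDC25B rose 1.58-fold and CDC25C 1.76-fold.

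Among the classical HDAC genes, HDAC3 rose 2.13-fold with SAHA (1.09 ± 0.14, adjusted p = 0.00309) and HDAC11, detected on 2 of 3 control arrays, 2.19-fold (1.13 ± 0.27), while HDAC1 (0.14 ± 0.12) and HDAC2 (−0.23 ± 0.17) did not pass. In that list of 8 genes 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.447). Of 10 genes in the list of histone acetyltransferases and bromodomain genes 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0568). The acetyltransferase genes KAT2A (2.51-fold, −1.33 ± 0.13), CREBBP (2.12-fold, −1.09 ± 0.12), EP300 (1.68-fold) and KAT5 (1.65-fold) fell. The riser was HEXIM1 (0.71 ± 0.21), a list member that encodes neither kind of protein, named after its value was seen. Of 11 genes of DNA and histone methylation 3 fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.21). SUV39H1 fell 2.77-fold (−1.47 ± 0.17) and SETDB1 2.13-fold, which both encode methyltransferases of histone H3, and the DNA methyltransferase gene DNMT1 fell 1.41-fold.

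Haematopoietic and leukaemia regulators gave 1 gene of 19 that rose with SAHA and 4 that fell, also adjusted over the list alone (camera adjusted p = 0.069). LMO2 fell 4.13-fold (−2.05 ± 0.46), LYL1 3.75-fold (−1.91 ± 0.26) and IKZF1 3.66-fold (−1.87 ± 0.22), 3 transcriptional regulators of blood cells, besides MYB, and PML rose 1.74-fold on its brightest probe (0.80), with −0.16 on another. Of 28 myeloid differentiation genes 0 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.86), namely the myeloid transcription factor genes CEBPE (3.28-fold, −1.71 ± 0.30) and SPI1 (3.10-fold, −1.63 ± 0.27). Of 20 erythroid genes only NFE2 passed, downward, also adjusted over the list alone (camera adjusted p = 0.356). None of 10 megakaryocytic genes, 7 T and B lymphocyte markers, 8 epithelial and stromal markers or 11 reference genes passed, nor any adjusted over the list alone. Their camera adjusted p-values were 0.794, 0.981, 0.973 and 0.794.

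Single immune and stress genes rose with SAHA, with no list passing. Of 17 type I interferon response genes 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.21), namely IFIT1 (2.78-fold, 1.47 ± 0.32, detected on 2 of 3 control arrays), IFI6 (2.25-fold) and ISG15 (1.81-fold). Of 14 antigen presentation genes 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.127), namely HLA-E (2.32-fold, 1.21 ± 0.22) and the peptide transporter gene TAP1 (2.16-fold). Of 18 genes of NF-kappaB and inflammatory cytokines 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.981). NFKB2 rose 3.20-fold (1.68 ± 0.20) and SOD2 1.72-fold, while NFKB1 fell 3.70-fold (−1.89 ± 0.25), the chemokine gene CXCL8 2.88-fold and the inhibitor gene NFKBIA 2.21-fold. Of 15 heat shock and chaperone genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.55). HSPA1A rose 4.02-fold (2.01 ± 0.33), DNAJB1 2.06-fold, HSPA1B 2.05-fold and HSPA5 1.81-fold, and HSPH1 fell 1.61-fold, where HSPA1A and HSPA1B are near-identical paralogs that probes need not tell apart. Of 4 metallothioneins, too few for the set test, MT1X rose 1.97-fold (0.98 ± 0.22) and 0 fell, with 3 and 0 adjusted over the list alone. Of 15 DNA repair genes 0 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.11), namely NBN (3.39-fold, −1.76 ± 0.21) and XRCC5 (1.52-fold). Of 18 cytoskeleton and adhesion genes only GSN, which encodes the actin-severing protein gelsolin, rose (1.74-fold, 0.80 ± 0.14, with 0.06 on another probe), also adjusted over the list alone (camera adjusted p = 0.357). Median, mean and test differed in sign for heat shock genes (median −0.06, mean 0.25, test upward), NF-kappaB genes (0.06, −0.04, downward) and epithelial markers (0.06, 0.05, downward).

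With MS-275, CDKN1A rose 9.09-fold (3.18 ± 0.30, n = 3 lines, adjusted p = 0.00558) and MYC fell 3.64-fold (−1.87 ± 0.42, adjusted p = 0.034). MYC did not pass without the detection filter (adjusted p = 0.063), without NB4 (0.199) or without U937 (0.154). FCRLA, a B cell gene related to Fc receptors, rose 12.8-fold (3.68 ± 0.27, adjusted p = 0.00523), with 1 of 3 control arrays detecting it, and FPR1, which encodes a chemotactic receptor of phagocytes, rose 8.89-fold (3.15 ± 0.53, adjusted p = 0.0166). The interleukin-1 genes rose, IL1B 6.70-fold (2.74 ± 0.44, adjusted p = 0.0157) and IL1A at least 6.09-fold (adjusted p = 0.000757), with IL1A detected on 0 of 3 and IL1B on 2 of 3 control arrays. PLD6 fell 7.77-fold (−2.96 ± 0.28, adjusted p = 0.00558), MNT, which encodes a MAX-binding antagonist of MYC, 5.43-fold (−2.44 ± 0.26, adjusted p = 0.00661), and SIN3A, which encodes the scaffold of an HDAC corepressor complex, 3.59-fold (−1.85 ± 0.27, adjusted p = 0.0121). Each of the 24 leading genes with MS-275 lost its call without at least 1 of the lines. Without U937 0 genes passed in limma and without NB4 2 did, so these losses do not single out any gene.

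The stress-response gene IER3 rose 7.70-fold with MS-275 (2.94 ± 0.31), PCED1B 7.28-fold (2.86 ± 0.22) and the kinase gene SGK1 7.01-fold (2.81 ± 0.41). SH2D2A, detected on 2 of 3 control arrays, rose 5.84-fold, TUFT1 5.78-fold and KLF2 5.66-fold, and HECW2, detected on 0 of 3 control arrays, rose at least 4.15-fold. Among genes that fell in all 3 lines were LRP8 (3.89-fold), SURF6 (3.85-fold), TFAP4 (3.73-fold), KLHL21 (3.72-fold), FOSL1 (3.59-fold), PHF23 (3.48-fold), AMER1 (3.42-fold) and ZMYND19 (3.20-fold). In all, 1325 genes changed with MS-275, 487 upward and 838 downward (36.8% up), of which 231 rose and 219 fell at least 2-fold, and 3412 had an unadjusted p under 0.05. With the arrays scaled to equal medians, 2215 genes changed, 373 upward and 1842 downward (16.8% up). The count depended on each line, with 2 genes (2 upward) without NB4, 237 (133 upward and 104 downward, 56.1% up) without K562 and 0 in limma without U937, and it was 2 without the cell line as a block. The larger number of falls was not seen without K562, and too few genes passed in the other runs to compare.

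Of 28 myeloid differentiation genes, 6 rose with MS-275 and 0 fell, or 10 and 0 adjusted over the list alone, with a median of 0.72. Besides FPR1, the transcription factor gene CEBPB rose 2.91-fold (1.54 ± 0.25, adjusted p = 0.0151), LGALS3 1.86-fold and the macrophage gene CD68 1.70-fold (0.77 ± 0.12), and the integrin gene ITGAM (1.92 ± 0.36) and MMP9 (1.91 ± 0.43) were named after their values were seen. LGALS3, ITGAM and MMP9 were detected on 2 of 3 control arrays, as was TNFSF10. The list had a camera adjusted p of 8.87e-06 and adjusted p = 0.26 with an estimated correlation. Of 18 HDAC inhibitor response genes 4 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.54 and a camera adjusted p of 3.99e-05 (adjusted p = 0.101 with an estimated correlation). The death ligand gene TNFSF10, which encodes TRAIL, rose 3.42-fold (1.77 ± 0.40), GLRX 2.23-fold and KLF6 1.90-fold. In the list of MYC and ribosome biogenesis 8 of 21 fell and 0 rose, or 11 and 0 adjusted over the list alone, with a median of −0.43 and a camera adjusted p of 1.46e-05 (adjusted p = 0.101 with an estimated correlation). PPAN fell 2.82-fold (−1.49 ± 0.14), NOP16 2.68-fold (−1.42 ± 0.13), RRS1 2.64-fold (−1.40 ± 0.14) and RRP9 2.24-fold (−1.16 ± 0.16).

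The interferon and antigen presentation lists passed upward with MS-275 at the preset correlation, with few members past the test. Of 17 type I interferon response genes 2 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.43 and a camera adjusted p of 0.000203 (adjusted p = 0.101 with an estimated correlation). IFIT1 rose 2.95-fold (1.56 ± 0.32) with 2 of 3 arrays detecting it in either group, and IFI35 rose 2.02-fold (1.01 ± 0.17). Of 14 antigen presentation genes 3 rose and 0 fell, also adjusted over the list alone, with a median of 0.37 and a camera adjusted p of 0.00249 (adjusted p = 0.142 with an estimated correlation), namely HLA-DMA (2.59-fold), HLA-E (2.02-fold) and the immunoproteasome gene PSMB8 (1.80-fold, 0.85 ± 0.14). Of 18 genes of NF-kappaB and inflammatory cytokines 2 rose and 0 fell (5 and 1 adjusted over the list alone), IL1B and the chemokine gene CCL2 (3.84-fold, 1.94 ± 0.50), both detected on 2 of 3 control arrays, with a median of 0.34 and a camera adjusted p of 0.0305 (adjusted p = 0.318 with an estimated correlation). Of 7 T and B lymphocyte markers 1 rose, CD2 (3.76-fold, 1.91 ± 0.31), also adjusted over the list alone, with a median of 0.33 and a camera adjusted p of 0.0305 (adjusted p = 0.266 with an estimated correlation). Of 12 death receptors and ligands 3 rose and 0 fell, also adjusted over the list alone, with a median of 0.29 and a camera adjusted p of 0.0446 (adjusted p = 0.26 with an estimated correlation). The members that rose were TNFSF10, TNFSF9 (2.94-fold, 1.56 ± 0.28) and TNFRSF10B (2.71-fold, 1.44 ± 0.34, with 0.29 on another probe).

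Among 12 linker and variant histones H1-10 rose 1.88-fold with MS-275 (0.91 ± 0.14), the only member to pass, also adjusted over the list alone, with a list median of 0.33 and a camera adjusted p of 0.0162 (adjusted p = 0.209 with an estimated correlation). Of 16 neuronal genes 3 rose and 0 fell (5 and 1 adjusted over the list alone), SYT11 (3.58-fold, 1.84 ± 0.22), VGF (2.19-fold) and SCG5 (2.07-fold, on 2 of 3 control arrays), with a median of 0.38 and a camera adjusted p of 0.0282 (adjusted p = 0.292 with an estimated correlation). Of 28 genes of G1/S and DNA replication 4 fell and 0 rose, also adjusted over the list alone, with a median of −0.24 and a camera adjusted p of 0.0446 (adjusted p = 0.433 with an estimated correlation). The phosphatase gene CDC25A fell 2.26-fold (−1.18 ± 0.15), UNG 2.03-fold, the cyclin gene CCNE1 1.89-fold and RRM2 1.76-fold. Of 10 genes in the list of histone acetyltransferases and bromodomain genes 2 fell and 0 rose (3 and 0 adjusted over the list alone), EP300 (1.74-fold, −0.80 ± 0.13) and BRD3 (1.51-fold), with a median of −0.29 and a camera adjusted p of 0.0446 (adjusted p = 0.318 with an estimated correlation). On probes detected on all 9 arrays the calls for G1/S, death receptors, acetyltransferases, NF-kappaB and neuronal genes ended, with adjusted p up to 0.140, 0.111, 0.126, 0.111 and 0.0766 over the alternatives. Leaving out U937 ended the first 4 of these, leaving out K562 ended those for death receptors and acetyltransferases, leaving out NB4 that for neuronal genes, and values without background correction that for death receptors. The T and B lymphocyte markers kept fewer than 5 genes on probes detected on all 9 arrays and could not be tested there.

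Other lists did not pass with MS-275, although single members did. Of 25 G2/M genes CCNA2 (1.59-fold) and CCNB1 (1.58-fold) fell and 0 rose, with 0 adjusted over the list alone (camera adjusted p = 0.0571). Of 15 DNA repair genes RAD54L fell 1.52-fold (0 adjusted over the list alone, camera adjusted p = 0.0579), and of 15 heat shock genes HSPH1 fell 1.83-fold, also adjusted over the list alone (camera adjusted p = 0.234). Of 16 p53 targets TNFRSF10B, SESN2 (2.05-fold) and GADD45A (1.74-fold) rose, also adjusted over the list alone (camera adjusted p = 0.138). Of 5 cyclin-dependent kinase inhibitors CDKN1A rose and CDKN1B fell 1.96-fold (−0.97 ± 0.21), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.174). Of 12 pro-apoptotic genes BIK rose 2.63-fold (1.39 ± 0.25), also adjusted over the list alone (camera adjusted p = 0.322), and BIK and SESN2 were detected on 2 of 3 control arrays. Of 10 megakaryocytic genes ITGA2B rose 1.59-fold, also adjusted over the list alone (camera adjusted p = 0.0553), and of 8 epithelial and stromal markers the endothelial and myeloid adhesion gene PECAM1 rose 2.14-fold (1.10 ± 0.23), also adjusted over the list alone (camera adjusted p = 0.101). Of 18 cytoskeleton genes the vimentin gene VIM rose 1.54-fold (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0615), and of 11 reference genes TBP fell 1.53-fold (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.161). Among 19 haematopoietic regulators KIT rose 1.79-fold, detected on 1 control and 2 MS-275 arrays, and MYB (1.93-fold) and LYL1 (2.21-fold) fell, also adjusted over the list alone (camera adjusted p = 0.646). No member passed, over all genes or adjusted over the list alone, among 9 anti-apoptotic genes, 8 classical HDACs, 11 methylation genes, 20 erythroid genes, 13 cholesterol genes and 4 metallothioneins. The camera adjusted p-values of the first 5 of these were 0.315, 0.404, 0.104, 0.224 and 0.518. HDAC1 (−0.02 ± 0.12), HDAC2 (−0.12 ± 0.17) and HDAC3 (0.27 ± 0.14) did not pass.

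Under scaling to equal medians the median change of all genes itself moved to −0.09 for SAHA against control, −0.14 for MS-275 against control and 0.03 for SAHA against MS-275. Relative to that shift the medians with SAHA were 0.82 for HDAC inhibitor response genes, 0.96 for cholesterol genes, −0.52 for MYC and ribosome genes and −0.44 for G1/S genes. With MS-275 they were 0.54 for HDAC inhibitor response genes, 0.70 for myeloid genes and −0.52 for MYC and ribosome genes.

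**Figure D2:**
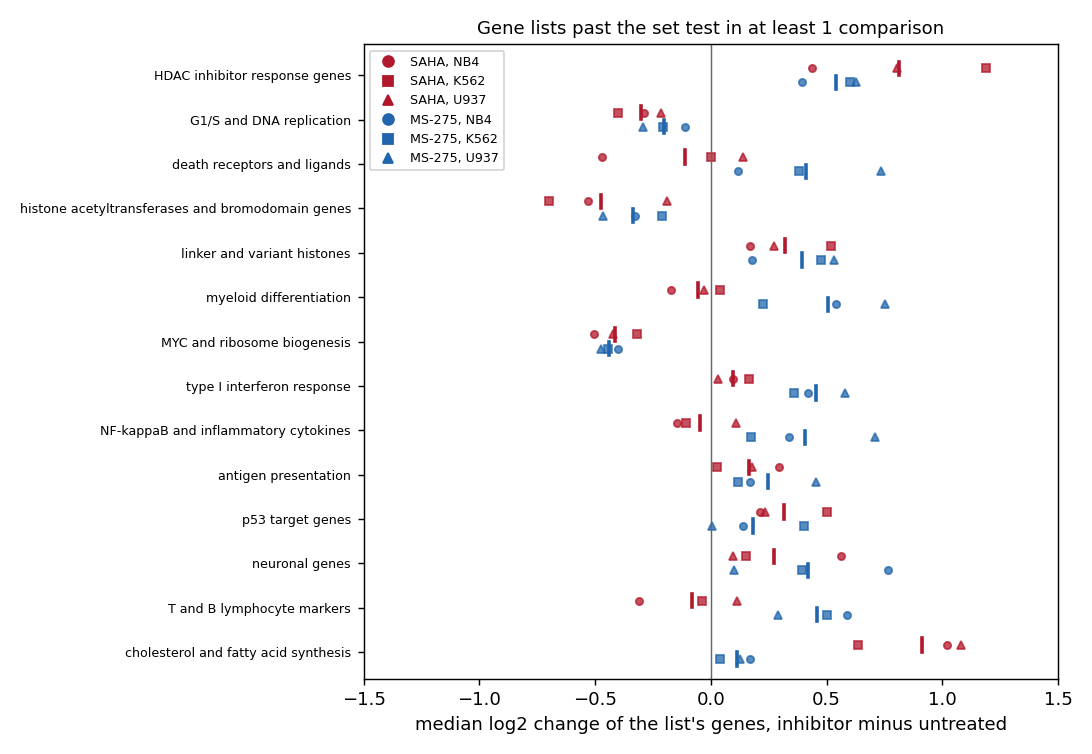
Median log2 change from the untreated control of the same line (x axis) for the 14 gene lists that passed the camera test in at least 1 comparison (y axis), with SAHA in red and MS-275 in blue, circles for NB4, squares for K562, triangles for U937 and a vertical bar at the mean of the 3 line medians. Myeloid genes lay between 0.22 and 0.75 with MS-275 and between −0.17 and 0.04 with SAHA, and cholesterol genes between 0.63 and 1.08 with SAHA. The median of cholesterol genes with MS-275 turns sign when arrays are scaled to equal medians.

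The inhibitors were then compared directly at the same dose and time, as 2 compounds that differ in the zinc-binding end of the molecule, a hydroxamic acid in SAHA and a benzamide in MS-275. IL18RAP, which encodes a subunit of the interleukin-18 receptor, was 15.0-fold lower with SAHA than with MS-275 (−3.91 ± 0.47, n = 3 lines, adjusted p = 0.00289), having fallen with SAHA (−2.03, adjusted p = 0.0205) and risen with MS-275 (1.88, adjusted p = 0.0444). The dehydrogenase gene DHRS9 was 10.4-fold lower with SAHA on its brightest probe (SAHA −1.40, MS-275 1.98), with −0.67 on the other, which differed by −0.03 from the control with SAHA. PCED1B was 9.32-fold lower (−3.22 ± 0.22, adjusted p = 0.00187), CCL2 7.79-fold and NFE2 7.43-fold lower (−2.89 ± 0.27, adjusted p = 0.00201). DACT3 was 14.3-fold higher with SAHA (3.83 ± 0.65, adjusted p = 0.008), the autophagy gene WIPI1 7.33-fold and the ciliary transport gene WDR19 7.10-fold. RAB40B was 7.01-fold higher with SAHA (2.81 ± 0.23, adjusted p = 0.00187), with a rise after SAHA (1.54) and a fall after MS-275 (−1.27), and ZNF324 was 6.09-fold higher (1.15 and −1.46). SIN3A was 4.79-fold higher with SAHA (2.26 ± 0.27) and FCRLA 5.95-fold lower (−2.57 ± 0.27). DACT3 was detected on 2 of 3 MS-275 arrays and CCL2 on 1 of 3 SAHA arrays. DACT3 and IL18RAP did not pass without U937, nor CCL2 without NB4.

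Of the 11228 genes, 2649 differed between the inhibitors, 1506 higher and 1143 lower with SAHA (56.9% higher), of which 593 and 386 differed at least 2-fold, and 4235 had an unadjusted p under 0.05. The count was 834 without NB4, 1724 without K562 and 511 without U937, and 72 without the cell line as a block. For some of the named genes the inhibitors were close. The difference of SAHA minus MS-275 was 0.02 for CDKN1A, with a 95% interval of −0.69 to 0.73, 0.05 for KLF2 (−0.49 to 0.60), −0.07 for FOSL1 (−0.49 to 0.34) and −0.12 for TFAP4 (−0.49 to 0.25). It was 0.08 for NOP16 (−0.22 to 0.38), −0.11 for RRS1 (−0.44 to 0.22), −0.04 for SYT11 (−0.56 to 0.47) and 0.05 for EP300 (−0.25 to 0.34). MYC was 2.05-fold lower with SAHA, with an interval of −2.01 to −0.06 and an adjusted p of 0.114. HDAC3 was 1.76-fold higher with SAHA (0.82 ± 0.14, adjusted p = 0.0087), while the differences were 0.16 for HDAC1 (−0.12 to 0.43) and −0.11 for HDAC2 (−0.52 to 0.30).

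**Figure D3:**
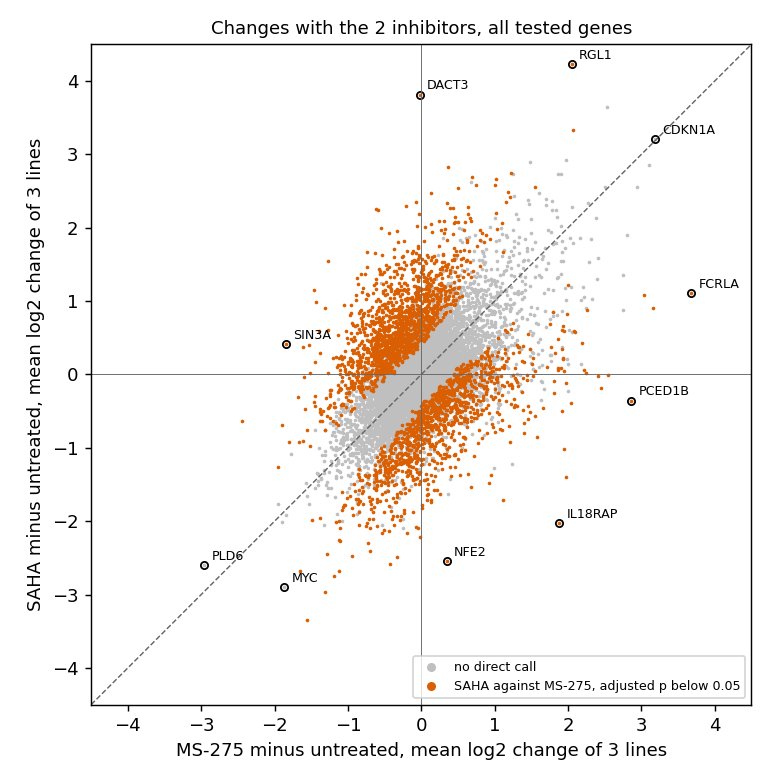
Mean log2 change over the 3 lines with MS-275 (x axis) and with SAHA (y axis), each against untreated cells, for the 11228 genes tested, with the 2649 genes that differed between the inhibitors in orange, the others in grey, a dashed line at equal change and circles around 10 labelled genes. CDKN1A lies near the dashed line at 3.18 and 3.20, whereas IL18RAP lies at 1.88 and −2.03.

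Of 28 myeloid differentiation genes 11 were lower with SAHA than with MS-275 and 0 were higher, or 16 and 0 adjusted over the list alone, with a median difference of −0.97. Its camera adjusted p was 2.36e-05, against adjusted p = 0.607 with an estimated correlation, and no other list passed. FPR1 was 4.74-fold lower with SAHA (−2.25 ± 0.53), SPI1 3.72-fold (−1.89 ± 0.27, adjusted p = 0.00469), CEBPE 3.48-fold (−1.80 ± 0.30), the lysozyme gene LYZ 1.73-fold and CD68 1.53-fold (−0.62 ± 0.12). Of 13 cholesterol genes 6 were higher with SAHA and 0 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.117), among them IDI1 (3.73-fold, 1.90 ± 0.17), INSIG1 (3.27-fold, with 0.31 on another probe), LSS (2.27-fold) and SREBF1 (1.91-fold). Of 15 heat shock genes 4 were higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.117), namely HSPA1A (3.87-fold, 1.95 ± 0.33), DNAJB1 (2.37-fold), HSPA1B (2.24-fold) and HSPA5 (1.43-fold). Of 18 NF-kappaB and cytokine genes 2 were higher and 5 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.117). NFKB2 was 3.64-fold higher, with CXCL8 4.63-fold, NFKB1 3.14-fold and NFKBIA 2.69-fold lower besides CCL2, and RELB (0.92 ± 0.22) and CXCL10 (−2.10 ± 0.60) were named after their values were seen. Of 19 haematopoietic regulators 1 was higher and 5 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.117), with PML 1.61-fold higher (−0.02 on another probe), LMO2 3.19-fold, MYB 2.88-fold, IKZF1 2.58-fold and KIT 1.69-fold lower, and RUNX1 (−0.84 ± 0.24) named after its value was seen. RELB and PML were detected on 2 of 3 MS-275 arrays, and KIT on 2 MS-275 arrays and 1 SAHA array.

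Among 21 MYC and ribosome genes 4 were higher and 3 lower with SAHA, also adjusted over the list alone (camera adjusted p = 0.904). MXD1 was 5.17-fold (2.37 ± 0.37) and RRP9 2.63-fold higher, MXI1 1.69-fold higher (0.23 on another probe), POLR1B higher (0.56 ± 0.16, named after its value was seen), and CAD 2.18-fold lower. Of 28 G1/S genes 3 were higher and 7 lower (4 and 7 adjusted over the list alone, camera adjusted p = 0.56), with CCNE1 2.39-fold and RRM2 1.54-fold higher, CTPS1 2.34-fold and TYMS 1.73-fold lower, and CDC6 (0.57 ± 0.14) named after its value was seen. Of 25 G2/M genes CDC25C was 1.79-fold higher and PLK1 1.94-fold lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.933). Of 18 HDAC inhibitor response genes TUBB3 was 3.08-fold and CRIP2 2.18-fold higher and TNFSF10 2.64-fold lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.496), with CRIP2 detected on 1 MS-275 array and TNFSF10 on 2 SAHA arrays. Of 5 cyclin-dependent kinase inhibitors CDKN2D was 2.94-fold higher and 0 were lower, also adjusted over the list alone (camera adjusted p = 0.674). Of 12 pro-apoptotic genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.347), BNIP3L 2.05-fold, BAD 1.87-fold, BNIP3 1.71-fold and BAK1 1.57-fold higher and BID 1.71-fold lower. Of 9 anti-apoptotic genes MCL1 was 2.20-fold higher, with −0.11 on another probe, and BCL2L1 2.57-fold and CFLAR 2.28-fold lower, also adjusted over the list alone (camera adjusted p = 0.652). Of 12 death receptors and ligands TNFSF9 was 1.99-fold higher and TNFSF10 and CASP8 (1.65-fold) lower, also adjusted over the list alone (camera adjusted p = 0.347).

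Of 10 genes in the list of acetyltransferases and bromodomain genes KAT6A was 1.42-fold higher with SAHA and KAT2A 2.17-fold, CREBBP 1.81-fold and BRD2 1.53-fold lower, also adjusted over the list alone (camera adjusted p = 0.757). Of 11 methylation genes the demethylase genes KDM3A (2.39-fold) and KDM5B (2.08-fold) were higher and SUV39H1 (2.03-fold) and SETDB1 (1.86-fold) lower, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.757), and KDM3A was detected on 2 of 3 MS-275 arrays. HDAC3 was the only one of 8 classical HDACs to differ, also adjusted over the list alone (camera adjusted p = 0.754). Of 17 interferon genes ISG15 was 1.64-fold higher and IFI35 2.11-fold and IFIT3 1.98-fold lower, the last detected on 1 of 3 SAHA arrays, also adjusted over the list alone (camera adjusted p = 0.153). Of 14 antigen presentation genes PSMB8 was 2.00-fold lower, also adjusted over the list alone (camera adjusted p = 0.56). Of 16 p53 targets RRM2B (2.19-fold), SESN2 (1.93-fold) and PPM1D (1.78-fold) were higher and 0 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.347). Of 15 DNA repair genes MRE11 was 1.74-fold higher and NBN 2.10-fold lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.866). Of 16 neuronal genes TUBB3 and SYP (1.60-fold, on 2 of 3 MS-275 arrays) were higher and VGF 2.05-fold lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.794), and of 18 cytoskeleton genes TUBB4B was 1.86-fold higher and TUBB6 1.43-fold lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.674).

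Of 20 erythroid genes only NFE2 differed, also adjusted over the list alone (camera adjusted p = 0.117), and of 10 megakaryocytic genes FLI1 was 1.71-fold and ITGA2B 1.40-fold lower with SAHA, also adjusted over the list alone (camera adjusted p = 0.117). Of 7 lymphocyte markers CD2 was 3.53-fold lower (camera adjusted p = 0.117) and of 8 epithelial and stromal markers PECAM1 was 3.61-fold lower (−1.85 ± 0.23, camera adjusted p = 0.347), with the same counts adjusted over the list alone. Of 11 reference genes TBP was 1.59-fold higher and PPIA 1.45-fold lower, also adjusted over the list alone (camera adjusted p = 0.56). None of 12 linker and variant histones (camera adjusted p = 0.757) and none of 4 metallothioneins differed, nor any adjusted over the list alone. Median, mean and test differed in sign for acetyltransferases (median 0.06, mean −0.10, test downward) and for MYC and ribosome genes (−0.11, 0.10, upward). They also differed for G2/M (−0.03, 0.04, downward), methylation (−0.01, 0.01, downward) and DNA repair genes (−0.03, 0.00, downward), whose medians turn sign when arrays are scaled to equal medians.

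The responses overlapped in part. Both comparisons used the same 3 control arrays, and 173 genes rose with both inhibitors where independent lists would share 58.2, and 392 fell with both against 98.7. With shared controls, independence is only a rough reference for these overlaps and for opposite changes. Opposite changes were found in 57 genes that rose with SAHA and fell with MS-275 (100.2 by independence), such as RAB40B and ZNF324, and in 8 that fell with SAHA and rose with MS-275 (57.4 by independence), such as IL18RAP. All these overlaps rest on the calls with MS-275, which numbered 2 without NB4, 237 without K562 and 0 without U937. Of the 173 genes that rose with both 24 differed between the inhibitors directly, as did 94 of the 392 that fell. Across genes the mean changes with SAHA and MS-275 correlated at r = 0.438 with a covariance of 0.142, and genes are not independent replicates. In 50 simulated sets of unchanged arrays that shared their controls, r averaged 0.498 and the covariance 0.0229.

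The last comparison asked whether the lines responded alike. With 1 array per line and treatment, values within a line carry no test. At least a 2-fold difference from the control was seen with SAHA in 1032 genes upward and 862 downward in NB4, 724 and 629 in K562, and 706 and 707 in U937. With MS-275 the numbers were 691 and 397 in NB4, 578 and 424 in K562, and 521 and 371 in U937. In NB4 alone HK1, which encodes hexokinase 1, was higher with both inhibitors (log2 difference 3.62 with MS-275, 5.14 with SAHA), although another of its probes gave −0.17 over the lines with SAHA, and the adhesion gene ICAM1 was higher (1.93 and 2.18). The homeobox gene HOXD13, detected in NB4 only, was lower there (−2.28 and −3.72), and NFE2L2, which encodes the oxidative stress regulator NRF2, was lower (−1.12 and −1.72). In K562 alone the protease gene LGMN was higher (2.50 and 2.69), as were NCCRP1 (2.33 and 2.84), ADAM19 (2.88 and 1.80) and RHBDL3 (2.28 and 2.20), the last 2 detected in K562 only. In U937 alone IL22RA2 was higher (3.71 and 1.00), as were BASP1 (1.41 and 1.27) and the thioredoxin inhibitor gene TXNIP (1.26 and 1.60), while MANEAL (−1.17 and −1.10) and the folate transporter gene SLC46A1 (−1.06 and −1.12) were lower. By this rule, at least 2-fold with both inhibitors in 1 line and a log2 difference under 0.5 with both in the other lines, 19 genes were higher and 9 lower in NB4 alone, 45 and 1 in K562 and 6 and 2 in U937. The rule asks for no detection in the other lines. A gene detected in 1 line only lies at background elsewhere and meets the limit there. These counts therefore mix expression limited to 1 line with a response limited to it.

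Lists were also followed line by line. With MS-275 the myeloid median was 0.54 in NB4, 0.22 in K562 and 0.75 in U937, and 0, 170 and 0 of 10000 random lists of the same size and expression were as high. With SAHA the cholesterol median was 1.02 in NB4, 0.63 in K562 and 1.08 in U937, with 0, 1 and 0 random lists as high. The median of MYC and ribosome genes with MS-275 was −0.40 in NB4, −0.44 in K562 and −0.48 in U937, with 1, 6 and 1 random lists as low. These counts treat genes as independent and rest on 1 array per line and treatment. They are not tests. In limma's F test of the interaction of line with treatment 0 of 11228 genes passed (171, or 1.52%, at an unadjusted p under 0.05), and 0 passed (507 unadjusted) in a model with the inhibitor difference as a further term, chosen after seeing the data. On simulated data the F test without that further term recovered 0% of line-dependent changes at log2 sizes of 0.5, 1 and 2. The model with the further term was not simulated. Across genes, changes with the same inhibitor in different lines correlated at 0.479 to 0.678 (mean 0.600, 6 pairs), and changes with different inhibitors in different lines at 0.196 to 0.331 (mean 0.260, 6 pairs). Within a line, where the inhibitors shared the control array, r was 0.311 to 0.502 (3 pairs), against 0.499 to 0.501 in simulated unchanged arrays that share a control. The covariance was 0.124 to 0.262 against 0.0688 to 0.0692.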

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

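The tests of single-probe hybridization, of a weaker response to one inhibitor, of an expression trend and of the response of 1 line were chosen only after the result was seen. Of 211 named genes, 15 stood out because both inhibitors moved them one way in one line and the opposite way in another. All but KDM5B, CD79B and HBB were named by the rule for single lines. It asks for a 2-fold change in 1 line and a log2 change under 0.5 in the others. Their gaps therefore follow from the naming, and the opposite movement is the sign of a small value. The difference between lines was not tested for any of the 15 genes beyond limma's interaction test, which 0 genes passed, with 171 at an unadjusted p under 0.05 and 507 in the model with a further term. In NB4 against another line the gap between mean log2 differences was 3.03 for HOXD13, 2.12 for HPDL, 2.00 for DACH1 and 1.75 for CHRM5, which were lower in NB4, and 2.28 for ICAM1, which was higher. HOXD13, DACH1 and CHRM5 were below detection on every array of the other lines, so the opposite movement there lies within the background. In K562 the gaps were 2.88 for NKD2, 2.83 for LGMN and 2.73 for NCCRP1, which were higher in K562, and 1.27 for LEPR, which was lower and detected in K562 only. In U937 IL22RA2 was higher, with a gap of 2.44, as was CD69, with 2.18, and SLC46A1 was lower, with 1.21. NKD2 in K562 and CD69 in U937 were below detection on the control array and above it on both treated arrays, so their gaps are set against background and do not give the size of the change. NKD2 and NCCRP1 in U937 and IL22RA2 in K562 were below detection on all arrays, so the opposite movement there lies within the background as well. The gap was 1.26 for KDM5B and 0.716 for CD79B, both lower in NB4 and higher in another line. For HBB it was 0.138, between lines in which it was below detection.

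Probes without a gene name here were not part of the gene tests. Of 1286 such probes past the detection filter, 262 (20.4%) changed with SAHA, 113 (8.79%) with MS-275 and 280 (21.8%) differed between the inhibitors. Named probes gave 23.1, 11.4 and 23.2%.

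SAHA and MS-275 changed partly different genes, and the changes in different lines correlated more with the same inhibitor than with the other. If single probes had hybridized differently, the 2 brightest probes of a gene would not shift together, but their SAHA minus MS-275 changes correlated at 0.745 across 1108 genes. If the normalization were the source, the gap of mean correlations of 0.339 would close under other ways to compute the values, and it stayed at 0.324 or above. A weaker form of the other inhibitor's response was tested only as changes scaled down by the same factor for every gene. Changes would then correlate between inhibitors across lines as the geometric mean of the correlations within inhibitors. The ratio was at most 0.544 (0.377 for NB4 and U937, 0.385 for K562 and U937), which argues against that form only. A shared response that is weaker or later to a different degree for different genes could also lower this ratio. That form remains open, since the inhibitors were compared only at the same dose and time. A response that differs between the compounds remains a hypothesis, and differences in RNA preparation or chip that follow the inhibitor may contribute, since no batch is recorded.

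Of 28 myeloid genes 11 were higher with MS-275 than with SAHA and 17 did not pass, and the list did not pass with an estimated correlation (adjusted p = 0.607). At the preset correlation it was the 1 list that passed, and all 10 splits of the 6 arrays gave at least as many lists. Of random lists matched on expression, at most 248 of 10000 had as low a median in any line (0 in NB4, 248 in K562, 0 in U937). This argues against a trend with expression level only with limits. The counts treat genes as independent, while the estimated correlation within the list was 0.147, and the list was picked on the same data. Scaling to equal medians gave a list median of −0.903, and the other ways to compute the values left it at −0.736 or below. Leaving out a line left it at −0.868 or below. The line medians were −1.01 in NB4, −0.24 in K562 and −1.31 in U937. These values are consistent with a difference between the inhibitors in the expression of some myeloid genes, as a hypothesis found on the same data.

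Among genes past the test, 29 were detected on 0 control arrays and on all 3 SAHA arrays against 10 lost in the same sense, a ratio of 2.9, and with MS-275 12 were gained and 4 lost. Over all genes, past the test or not, 42 were gained and 18 lost with SAHA, and 26 gained and 16 lost with MS-275. Whether genes silent in untreated cells came on more often than active genes went off is left open. A shift of the detection limit with treatment cannot be excluded, since the ratio of 2.9 fell short of the 3 set beforehand and treated arrays detected more probes in every line.

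Other groupings of the 6 arrays of each comparison were also tested. With 10 splits the share cannot fall under 0.05. The real split gave 2665 genes for SAHA against control, 1325 for MS-275 against control and 2649 for SAHA against MS-275, with 0 as the highest other in each, so 1 of 10 splits reached the real count. For lists the real split gave 7, 12 and 1, against 6, 13 and 5 as the highest other, so 1, 2 and 10 splits reached it. The number of lists passing therefore does not set the real grouping apart for MS-275 against control or between the inhibitors. Among the 4 splits that part all 3 lines the highest others were 3, 9 and 5 lists and 0 genes, while the remaining splits put both arrays of a line in one group. For line dependence all 27 choices of 1 array per line as the control gave as many genes as the real one, which was 0, with 0 as the highest other. Any choice reaches a count of 0, so this comparison cannot decide whether the lines differed.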

How the results depend on the processing

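The model with the inhibitor difference as a further term was chosen after seeing the data. No change of a named gene past the test turned its direction under any alternative run. For the leading genes, named for the same sign in all 3 lines, leaving out a line could not turn it. The balance of changed genes with MS-275 did turn, from 487 higher and 838 lower to 133 and 104 without K562, and the median of cholesterol genes with MS-275 turned sign with equal medians relative to the shift of all genes as well (0.05 to −0.05). The authors' values and no background correction are identical by construction. Of 24 leading genes with SAHA 0 lost their call under another way to compute the values, of 24 with MS-275 1 did, MYC without the detection filter (adjusted p = 0.063), and of 10 between the inhibitors 0 did, whereas leaving out a line ended 6, 24 and 3 of these calls. With MS-275 0 genes passed in limma without U937, so all 24 of its calls had to end. Genes changed with SAHA, with MS-275 and between the inhibitors numbered 1080, 450 and 979 with a 2-fold minimum, by its construction, and 101, 2 and 72 without the replicate block that pairs arrays of a line. On only the 6 arrays compared, which leaves fewer residual degrees of freedom, the counts were 701 for MS-275 and 1733 between the inhibitors, and scaling to equal medians gave 2215 for MS-275, where the cause was not tested. Leaving out a line gave 887 to 1681, 0 to 237 and 511 to 1724 genes, with fewer arrays tested. All other settings kept these counts within 1.5-fold. Line-dependent genes numbered 0 in limma under every setting in which that test was run, with 52 to 507 at an unadjusted p under 0.05. It was not run without the block or on only the 6 arrays compared. Under the main settings the test recovered 0% of simulated changes, and its other settings and the model with a further term were not simulated. A count of 0 throughout therefore shows no stability.

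Lists passed in 0, 0 and 0 cases with an estimated correlation and in 15, 16 and 3 with fry, which asks another question than camera. On probes detected on all 9 arrays they numbered 3, 6 and 1, with fewer genes per list. Leaving out a line gave 6 to 10, 10 to 13 and 1 to 4 lists. Some lists lost their call although their estimated correlation lay under the preset 0.01. For antigen presentation with MS-275 the estimate was −0.0383, and the unadjusted camera p still went from 0.000444 to 0.0202. For such lists the lost call does not come from a higher correlation between genes. Other estimates lay above the preset value, such as 0.147 for myeloid genes.

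Counts of 2-fold differences per line without background correction, that is with the authors' values, were 543 and 1095 for MS-275 and SAHA in NB4, 425 and 728 in K562 and 446 and 800 in U937. Uncorrected background compresses the log2 differences of weak signals, and this ratio of signal to background limits every fold near the detection limit. On probes detected on all 9 arrays MS-275 gave 625, 616 and 524 genes in NB4, K562 and U937, with fewer genes counted, and with an offset of 50 it gave 623 in K562. At a 1.5-fold minimum the counts were 2827 and 3810 in NB4, 2913 and 3116 in K562 and 2508 and 3259 in U937. The mean correlation of changes with the same inhibitor in different lines was 0.679 on probes detected on all 9 arrays, where the cause was not tested.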

Other observations

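None of the tests in this part was chosen after the result was seen, except for the counts of neighbours with MS-275 and for lower genes. In K562, a line with erythroid and megakaryocytic features, 3 single globin and platelet genes differed between the inhibitors. HBB differed from the control by 1.82 (log2) with MS-275 and −0.22 with SAHA, and HBD by 1.36 and −0.52, both detected in K562 only. The erythroid list had a median of −0.43 with SAHA in K562, and 12 of 10000 random lists were as low, but with MS-275 it was 0.09, with 2071 as high. The megakaryocytic list had medians in K562 of 0.27 with MS-275 and −0.01 with SAHA, with 723 and 5014 random lists as high. Random lists treat genes as independent, while the estimated correlation within the erythroid list was 0.411, so these counts are no test. TUBB1, a tubulin gene of platelets detected in K562 only, differed by −3.21 with SAHA and −0.25 with MS-275. In U937 the B cell receptor gene CD79A differed by 1.70 with MS-275 and −1.04 with SAHA. The collagen gene COL1A1 differed by 2.56 with MS-275 and 2.60 with SAHA in K562. With 1 array per line and treatment none of these values was tested singly, and 0 genes passed limma's interaction test.

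Inflammatory lists differed in size between the lines with MS-275. The median of NF-kappaB and cytokine genes was 0.34 in NB4, 0.18 in K562 and 0.71 in U937, and 44, 822 and 0 of 10000 random lists were as high. Interferon genes had medians of 0.42 in NB4, 0.36 in K562 and 0.58 in U937, with 8, 30 and 0 random lists as high. The HDAC inhibitor response list had medians with SAHA of 0.44 in NB4, 1.19 in K562 and 0.81 in U937, with 38, 0 and 0 random lists as high. The counts of random lists are no test here either, and the difference between lines was not tested for these lists.

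A further hypothesis was that neighbouring genes share the response, so that genes next to each other on a chromosome would rise together with SAHA. Of 10688 adjacent pairs of tested genes, 165 had both members higher with SAHA. Shuffled positions gave 153 on average, with the central 95% between 133 and 174, and 145 of 1000 shuffles gave as many, so the number did not exceed chance. For genes lower with SAHA the number was 163 against 148, reached by 102 shuffles. With MS-275 35 pairs were both higher against 20 by shuffling, reached by 0 of 1000, and 75 were both lower against 59.7, reached by 23.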
